A study of Drosophila melanogaster with 87 samples.

How the data were processed

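Messenger RNA was measured by sequencing in libraries of sorted midgut cells. Per the labels, midguts of female flies were removed and dissociated and cells were sorted by their fluorescent marker. RNA was extracted with a PicoPure kit and amplified with a RiboAmp HS Plus kit, and libraries were made with a TruSeq RNA kit. Amplification of small RNA amounts can add spread that sequencing depth does not reduce. Whole-midgut libraries were read at 72 bases on a GAIIx and regional libraries at 50 bases on a HiSeq, per the series description. Whole-midgut and regional libraries differ in instrument, read length and, for EE, marker, so that they were fitted separately. The labels list 87 samples, of which 71 had a value column. The other 16, of 1 further sorted population, are not analysed here.

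Per the submitters' processing notes, the genome build was BDGP5 and the tools named were FastQC, TopHat2 2.0.9, Bowtie2 2.1.0, SAMtools 0.1.19, HTSeq 0.5.4p5 and DESeq. The step that made the values is not given in the sources used here. The 52 deposited columns of the regions and of whole-midgut VM hold RPKM. In each column the values are whole multiples of a step set by the library and the gene, which gave each gene's divisor and each library's whole reads. This solved 14293 genes (99.958% of the genes seen in at least 3 libraries with a tolerance of 0.005 reads). The other 19 deposited columns, whole-midgut ISC, EB, EC and EE, are treated as a score, since their divisor is not the gene's own. They hold whole reads, scaled to a common library total (12499 genes, 99.976% solved) and divided by a number that followed neither the gene's own divisor nor its exon length. Across genes its log correlation with the divisor of the RPKM columns was 0.0177, and with the union of the gene's exons 0.00998, against 0.923 for the divisor of the RPKM columns. Of 1079 divisors above 12000 bases, 1061 equal the divisor of another gene in the RPKM columns and 0 that of the gene itself. Levels, and comparisons with VM, would therefore be wrong gene by gene, while a gene's ratios among the 19 columns are unaffected apart from the pseudocount. The whole-midgut values used here are the deposited values times the divisor used over the gene's own divisor, a choice made after the values were seen, and the deposited values are an alternative. Rescaling raised the correlation of whole-midgut with regional log means from 0.7207 to 0.9504 in ISC, 0.6722 to 0.9079 in EB, 0.7098 to 0.9147 in EC and 0.6987 to 0.8848 in EE, over 12478 genes, which are not independent replicates. Without an own divisor 1379 genes were left out of the whole-midgut set, 13 at 1 or more in at least 2 libraries. Unsolved genes held 41.9% and 30.0% of the value of whole-midgut VM and at most 21.0% elsewhere. In simulated data 99.97% of 11370 solved genes came back with exact reads. Symbols were matched by gene identifier for 15001 of 15682 genes, and the other 681 are not named.

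Assigned reads per library, from the recovered reads, were 5088394 to 80655887 in the whole midgut and 10444983 to 43340856 in regions. The 10 most abundant genes took 8.24% to 39.3% of a whole-midgut library and 10.2% to 38.4% of a regional library, and 5823 to 7211 and 5186 to 7447 genes reached 1 RPKM. In the shallowest library a gene near 1 RPKM rests on few reads, so that small changes of such genes were not detectable. Replicate libraries correlated at 0.7232 to 0.9975 on the log scale across genes. Replicates were compared by a chi-square test of their reads, and a pair below 2 per degree of freedom, a threshold set after the values were seen, was counted as 1 sample through its mean. This merged ISC replicates 1 and 2 (1.16, formally still above sampling noise) and left 20 whole-midgut samples.

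Values were analysed as log2(RPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes with a trend and robust estimation), on genes at 1 or more in at least 2 libraries of the set. All groups of a set entered 1 fit and shared its estimate of spread, with 11 residual degrees of freedom in the whole midgut and 25 in regions. Tests were two-sided and adjusted by Benjamini and Hochberg at 0.05. Contrasts were each cell type against the mean of the other 4, ISC against EB, and infected against uninfected within each of 4 types. To these came an F-test of the difference in infection response between the types, each EC region against the mean of the other 4 and an F-test across regions within each type. The tests assumed in advance allowed for counts or for normalized values, and those for normalized values were used. Before the data were examined, 31 gene lists and the rule for named genes were fixed. The rule takes the marker genes and, per whole-midgut cell type contrast, up to 8 highest and 3 lowest called genes (6 and 6 for ISC against EB). Per infection contrast it takes up to 8 and 8, per EC region up to 6 higher and per region of the other types up to 2. Per list it takes up to 4 called members. Marker genes apart, and except where stated, the libraries of the groups compared must not overlap. Genes without a symbol or named by a bare CG or CR number are passed over. Lists were tested with camera (limma), with its preset correlation of 0.01 and with the correlation estimated per list, adjusted over the tests of a family. With the estimated correlation 0 of 130 calls held among the 360 tests of cell types, 0 of 39 among 124 of infection and 0 of 24 among 145 of EC regions. A list is called here by its preset result, and both adjusted p-values are given. The lists, among them muscle, haemocyte, fat body, ovary and tracheal genes, include cell types that a gut preparation could hold. Libraries were also compared with every other library of their set, and those nearest to another cell type were left out in an alternative chosen after the values were seen.

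Fits were tested on simulated values with known changes. Of changed genes at 2-, 4- and 8-fold, the infection contrast in EB called 7.46%, 61.2% and 78.8% and the F-test of the difference 0%, 20.9% and 56.1%. Whole-midgut ISC called 16.4%, 74.6% and 89.4%, EC of R3 43.3%, 88.1% and 92.4% and regional EC 91.0%, 98.5% and 100%. Thus 2-fold changes were mostly missed in the whole midgut, perhaps more at low levels. Alternatives fixed before the data were examined were a pseudocount of 0.1, no filter on low values, quantile normalization, a fit of the compared groups alone, at least 2-fold changes, a replicate block, an estimated correlation for lists and each library left out in turn. Chosen after seeing the data were the deposited values, voom on recovered reads, fits without the libraries nearest to another type, without VM or without EB, and ISC replicates kept separate. Same-numbered regional libraries of a type deviated together (in EB and EC in 10 of 10 pairs of regions, from the data and not the labels), so that a replicate block within each type and means of such libraries over regions as samples were added. Other splits of the samples were counted over 100 draws. Figures and tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.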

Results

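Messenger RNA was profiled in cell types sorted by fluorescence from dissociated midguts of female Drosophila melanogaster. The types were intestinal stem cells (ISC, marked by Delta-Gal4), enteroblasts (EB, their Notch-responsive daughters, marked by Su(H)-Gal4), absorptive enterocytes (EC, marked by Myo1A-Gal4), hormone-secreting enteroendocrine cells (EE, marked by Rab3-YFP in the whole midgut and by Pros-Gal4 in regions) and visceral muscle (VM, marked by How-Gal4). The 5 types were sorted from whole midguts (21 libraries in 9 groups) and, in duplicate, from each of 5 midgut regions numbered R1 to R5 from anterior to posterior (50 libraries in 25 groups). In the whole midgut, ISC, EB, EC and EE were also sorted from animals infected with Pseudomonas entomophila, a bacterial pathogen of the fly gut. Uninfected whole-midgut groups held 2 ISC, 3 EB, 2 EC, 2 EE and 2 VM samples, and infected groups held 2 ISC, 2 EB, 2 EC and 3 EE samples. ISC replicates 1 and 2 differed by little more than sampling noise (chi-square per degree of freedom 1.16 against a median of 225.5 over 40 replicate pairs) and were counted as 1 sample. Each type had its own marker, so that effects of type and of the marked fly line cannot be told apart. Assigned reads were 60.7% to 96.8% of a library's total (uninfected EC 73.2% and 80.9%, infected 95.7% and 96.8%), which can shift levels.

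Levels are in RPKM, as mean ± SD with n libraries. Log2 fold changes are limma estimates on log2(RPKM + 1) with their standard errors. They understate the change of genes at low levels. The adjusted p-values are Benjamini-Hochberg adjusted over the 9083 genes tested in the whole midgut or the 9735 tested in regions. The labels do not say that replicates came from separate animals, so that p-values measure the spread between these samples, which may be technical. Same-numbered regional libraries of 1 type deviated from their group means together, in 10 of 10 pairs of regions in EB and EC, 9 in EE and VM and 6 in ISC (correlation above 0.1), so that they are not fully independent. With their means over regions taken as samples, the regional tests of cell type called 3525 genes in ISC, 1809 in EB, 907 in EC, 2574 in VM and 1284 in ISC against EB, fewer than the numbers given below, and the EE count moved by less than 1.5 times. Trypsins, Jonah proteases (Jon genes), lysozymes (Lys genes), glutathione transferases (Gst genes), Hsp70 genes and transfer RNAs belong to families with near-identical copies that can share reads, and values of their single members are uncertain. The same holds for overlapping and antisense genes, mitochondrial ones included, since no use of strand is stated. In 3 of 21 whole-midgut and 4 of 50 regional libraries, the library with the highest correlation was of another cell type. These were both whole-midgut VM libraries (nearest to EB and to ISC), infected EC replicate 2 (nearest to infected ISC), EE R3 replicate 1, both VM R2 libraries and VM R4 replicate 2.

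The genes behind the sorting markers were examined in every group. Delta (FBgn0000463), the Notch ligand of stem cells, stood at 27.3 ± 0.646 in ISC (n = 2), at 1.41 ± 0.347 in EB (n = 3) and at 0.910 ± 0.137 in EC (n = 2). It was higher in ISC than in the other types in the whole midgut (log2 fold change 3.32 ± 0.96, adjusted p = 0.0219) and in regions (2.51 ± 0.20, adjusted p = 5.37e-11). The 2 whole-midgut VM libraries differed widely, at 0.288 and 95.8 for Delta, 0.136 and 18.0 for Rab3 and 0.125 and 1.06 for pros, where the EE libraries held Rab3 at 8.32 and 14.9 and pros at 0.893 and 1.26. Rab3 (FBgn0005586), a synaptic vesicle GTPase, and pros (FBgn0004595), the transcription factor Prospero, were higher in EE in the whole midgut (2.44 ± 0.65, adjusted p = 0.0187, and 0.72 ± 0.21, adjusted p = 0.0322) and in regions (4.72 ± 0.26, adjusted p = 2.97e-15, and 2.71 ± 0.14, adjusted p = 8.49e-16). In EE of R3 the 2 libraries held Rab3 at 1.42 and 84.7 and pros at 0.229 and 8.17. The whole-midgut calls of Delta and Rab3 were lost without either sample of their own type (adjusted p = 0.155 to 0.157 for Delta, and 0.0922 and 0.201 for Rab3). The call of pros was lost without any of several libraries. Transcripts of the other drivers did not mark their cells. Su(H) (FBgn0004837) in EB (0.29 ± 0.24, adjusted p = 0.532), Myo31DF (FBgn0086347, the gene of Myo1A) in EC (0.65 ± 0.43, adjusted p = 0.4) and how (FBgn0264491) in VM (0.67 ± 0.31, adjusted p = 0.258) did not pass the test in the whole midgut. In regions Su(H) was lower in EB (-0.29 ± 0.09, adjusted p = 0.0109), how was lower in VM (-0.20 ± 0.07, adjusted p = 0.0186) and Myo31DF did not pass (-0.16 ± 0.13, adjusted p = 0.374). The regional calls of Su(H) and how were lost with means of same-numbered libraries as samples, and that of how without VM R1, R2 or R4 replicate 1.

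**Figure D1:**
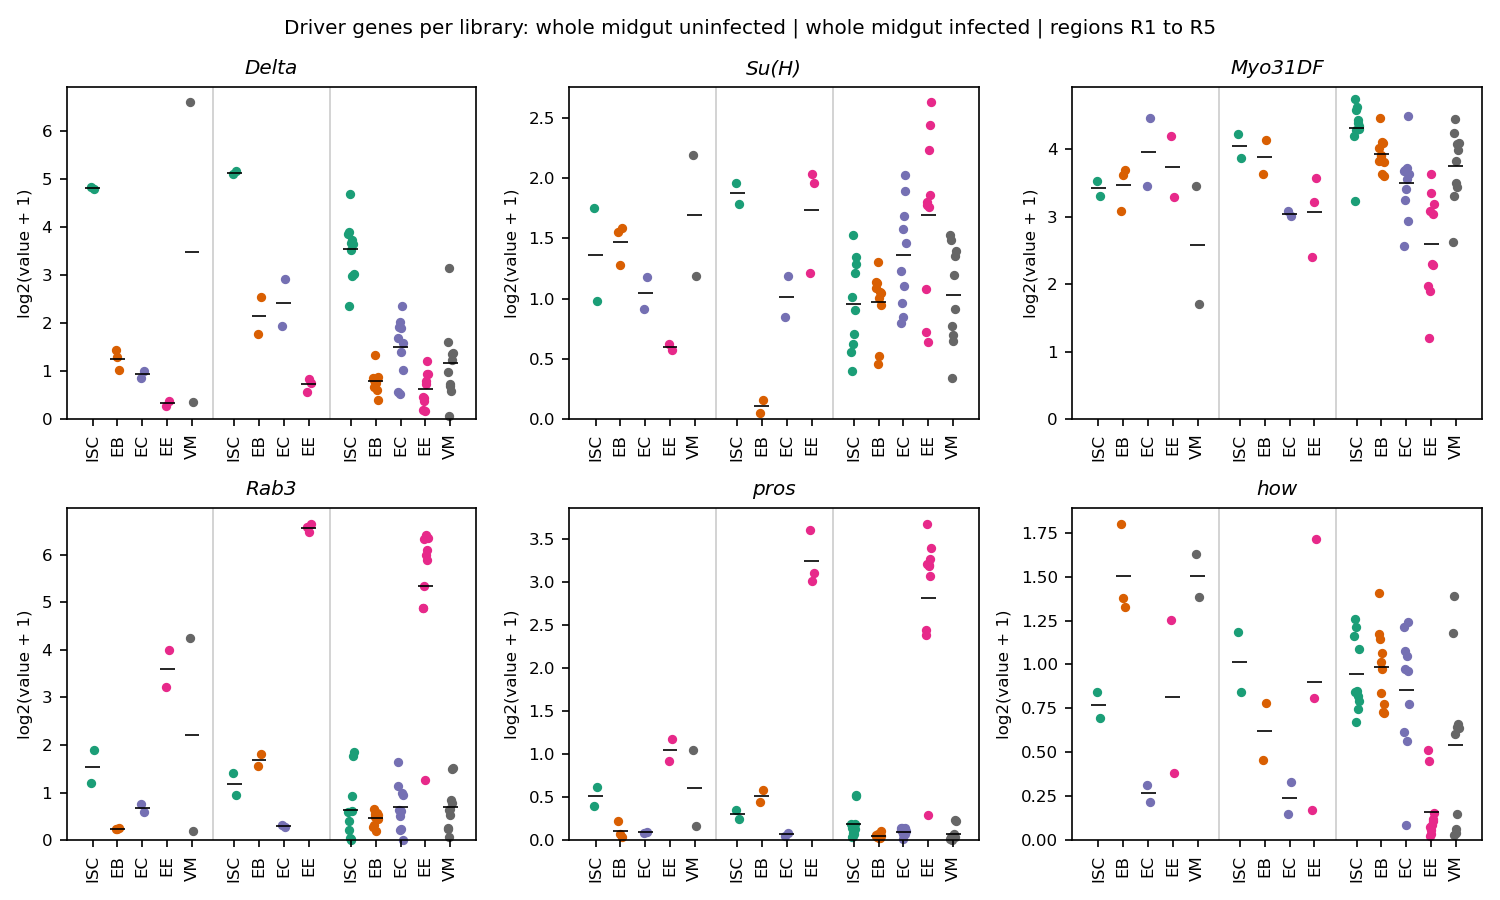
Levels of the 6 genes behind the sorting markers in each library, as log2(RPKM + 1), by cell type in uninfected whole midguts, infected whole midguts and regions R1 to R5 pooled. Points are libraries and horizontal lines are means. Delta is high in ISC, and Rab3 and pros are high in EE, but 1 whole-midgut VM library holds Delta at 95.8 RPKM and Rab3 at 18.0 RPKM, above both uninfected whole-midgut EE libraries. Su(H), Myo31DF and how do not set their types apart.

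Stem cells were compared with the mean of the other 4 types to find the genes that set them apart. In the whole midgut 949 genes were higher and 1200 lower in ISC. The highest were DptB (FBgn0034407), which encodes an antibacterial diptericin (74.8 ± 1.46 RPKM, n = 2, against at most 0.0983 in the other 9 libraries; 6.21 ± 1.85, adjusted p = 0.0257), E(spl)malpha-BFM (5.68 ± 0.69, adjusted p = 0.0002), the glutathione transferase GstD2 (4.82 ± 0.95), the nucleosome-binding protein Df31 (4.67 ± 0.81), mt:tRNA:Asn-GTT (4.67 ± 0.55), babos (4.36 ± 0.52), E(spl)m7-HLH (4.22 ± 0.45) and E(spl)mbeta-HLH (4.20 ± 0.68). The lowest were Nazo (-6.05 ± 0.87), Acbp5, an acyl-CoA-binding protein (-5.83 ± 0.58), and the trypsin thetaTry (-5.46 ± 1.14). Of 11 progenitor markers 7 were higher and 4 did not pass (9 higher when adjusted over the list alone), led by Sox100B (3.97 ± 0.90), Delta and heca (3.09 ± 0.44; adjusted p = 7.51e-05, and adjusted p = 0.609 with an estimated correlation). Of 11 Notch target genes of the Enhancer of split class 9 were higher and 2 did not pass (10 adjusted over the list alone; adjusted p = 2.51e-07, and adjusted p = 0.581 with an estimated correlation). Of 31 cell cycle genes 12 were higher and 19 did not pass (13 adjusted over the list alone; adjusted p = 1.17e-05, and adjusted p = 0.681 with an estimated correlation), among them Cdk1 (3.21 ± 0.70), Incenp (3.19 ± 0.52) and the phosphatase string, stg (2.41 ± 0.55). Of 12 EGFR pathway genes 6 were higher and 6 did not pass (7 adjusted over the list alone; adjusted p = 0.000131, and adjusted p = 0.581 with an estimated correlation), led by the ligand protease rho (2.70 ± 0.27) and the ligand spi (2.34 ± 0.66). Of 40 digestive enzymes 1 was higher and 23 lower (1 and 29 adjusted over the list alone; adjusted p = 5.77e-08, and adjusted p = 0.617 with an estimated correlation). Of 9 enterocyte markers 6 were lower and 3 did not pass (6 adjusted over the list alone; adjusted p = 0.000347, and adjusted p = 0.581 with an estimated correlation), led by mex1 (-3.67 ± 0.53) and nub (-3.36 ± 0.62). Higher genes made up 44.2% of the calls, 56.3% after quantile normalization and 55.4% on the deposited values. The count was 531 without the merged ISC sample and 469 without ISC replicate 3. DptB, GstD2 and thetaTry lost their call in at least 1 of these fits. It was 3327 without the 3 whole-midgut libraries nearest to another type.

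The regional ISC libraries, from other sorts, gave 1957 genes higher and 4086 lower. Of 11 progenitor markers 10 were higher and 1 did not pass (10 adjusted over the list alone; adjusted p = 2.85e-08, and adjusted p = 0.581 with an estimated correlation), led by Delta (2.51 ± 0.20), the neuroblast scaffold mira (2.51 ± 0.15) and Sox100B (2.48 ± 0.34). Of 30 cell cycle genes 25 were higher, 1 lower and 4 did not pass (26 and 1 adjusted over the list alone; adjusted p = 8.21e-11, and adjusted p = 0.582 with an estimated correlation). Of 19 ribosome biogenesis genes 17 were higher and 2 did not pass (17 adjusted over the list alone; adjusted p = 1.68e-08, and adjusted p = 0.581 with an estimated correlation), led by Fib (1.71 ± 0.20) and nop5 (1.59 ± 0.20). Of 12 Notch target genes 11 were higher and 1 lower (11 and 1 adjusted over the list alone; adjusted p = 7.71e-06, and adjusted p = 0.581 with an estimated correlation). Of 8648 genes tested in both sets, 632 were higher in ISC in both, where 201.6 would be shared by independent lists, and 997 were lower in both against 492.2. Higher genes made up 32.4% of the regional calls and 55.3% after quantile normalization.

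Enteroblasts differed from the other types at 483 genes in the whole midgut, 233 higher and 250 lower. The highest were E(spl)m3-HLH (FBgn0002609; 305 ± 64.4 RPKM, n = 3, against 1.10 to 186 in the other types; 4.03 ± 0.47, adjusted p = 0.000399), Tmhs (3.87 ± 0.41), the prophenoloxidase PPO2, a haemocyte marker (3.36 ± 0.80), gas (2.69 ± 0.40), the zinc finger repressor klu (2.12 ± 0.24), Uhg7 (2.12 ± 0.31), the adhesion receptor Cirl (2.07 ± 0.25) and the Notch-modifying glycosyltransferase fng (2.02 ± 0.34). The lowest were the sterol carrier Npc2b (-5.10 ± 0.51), Jon25Biii (-4.63 ± 0.80) and Jon25Bii (-4.26 ± 1.02). Of 11 Notch target genes 4 were higher and 7 did not pass (4 adjusted over the list alone), namely E(spl)m3-HLH, E(spl)malpha-BFM (3.43 ± 0.59), E(spl)mbeta-HLH (2.71 ± 0.59) and klu. The list had a median of -0.04 and a mean of 1.04 (adjusted p = 0.0445, and adjusted p = 0.646 with an estimated correlation). Of 12 peptide hormones 6 were lower and 6 did not pass (9 lower adjusted over the list alone; adjusted p = 1.88e-06, and adjusted p = 0.581 with an estimated correlation), led by CCHa1 (-5.48 ± 1.2) and AstA (-5.38 ± 1.1). Of 40 digestive enzymes 12 were lower and 28 did not pass (26 lower adjusted over the list alone; adjusted p = 2.17e-15, and adjusted p = 0.581 with an estimated correlation), led by Jon25Bi (-4.79 ± 0.99). Of 7 haemocyte markers 1 was higher, PPO2, and 6 did not pass (1 adjusted over the list alone; adjusted p = 0.236, and adjusted p = 0.852 with an estimated correlation). Higher genes made up 48.2% of the calls, 69.3% with voom on recovered reads and 66.6% on the deposited values. The count was 126, 90 and 126 without EB replicate 1, 2 or 3, 252 and 230 without the merged ISC sample or ISC replicate 3, and 292 and 285 without EC replicate 1 or 2. It was 1460 without VM replicate 1 and 1736 without the 3 libraries nearest to another type. PPO2 and Jon25Bii lost their call in several of these fits.

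In regions 2273 genes were higher and 2344 lower in EB. Of 12 Notch target genes 5 were higher, 1 lower and 6 did not pass (5 and 2 adjusted over the list alone; adjusted p = 0.345, and adjusted p = 0.882 with an estimated correlation), led by E(spl)mbeta-HLH (2.06 ± 0.42), E(spl)m3-HLH and E(spl)malpha-BFM (1.42 ± 0.41). Of 19 Imd pathway genes, which carry the response to bacterial peptidoglycan, 11 were higher, 2 lower and 6 did not pass (11 and 2 adjusted over the list alone; adjusted p = 0.0398, and adjusted p = 0.581 with an estimated correlation). The amidase PGRP-SC2 was lower (-3.06 ± 0.79), and PGRP-SD (1.00 ± 0.20), key (0.92 ± 0.12) and the receptor PGRP-LC (0.87 ± 0.13) were higher. The whole-midgut and regional EB lists shared 118 higher genes, against 54.81 for independent lists, and 142 lower genes against 58.97.

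A direct comparison of ISC with EB asked which genes differ between a stem cell and its daughter. In the whole midgut 524 genes were higher and 581 lower in ISC. The highest were the hormone genes CCHa1 (FBgn0038199; 227 ± 9.96 RPKM, n = 2, against 0 to 2.86 in EB, n = 3; 6.94 ± 1.60, adjusted p = 0.0143), CCHa2 (5.67 ± 1.22) and Tk (5.22 ± 1.03), with GstD2 (5.69 ± 1.10) and the mitochondrial tRNAs mt:tRNA:Gly-TCC and mt:tRNA:Asn-GTT, which were listed at 0 in the EB libraries. The lowest were Nazo (-6.95 ± 1.02), the sterol carrier Npc2e (-5.95 ± 0.90), Acbp5 (-5.90 ± 0.68), Takl1 (-5.33 ± 0.62), the mucin-related Mur29B (adjusted p = 0.00941) and Srg3 (-4.81 ± 1.11). Of 12 peptide hormones 5 were higher and 7 did not pass (9 adjusted over the list alone; adjusted p = 1.01e-05, and adjusted p = 0.581 with an estimated correlation). Of 15 neuroendocrine machinery genes 2 were higher in ISC and 13 did not pass (2 adjusted over the list alone; adjusted p = 0.00594, and adjusted p = 0.681 with an estimated correlation), and Rab3 stood at 2.01 ± 0.983 in ISC against 0.180 ± 0.0122 in EB. Of 9 enterocyte markers 6 were lower and 3 did not pass (6 adjusted over the list alone; adjusted p = 0.000111, and adjusted p = 0.581 with an estimated correlation), led by nub (-3.77 ± 0.73). The Notch targets E(spl)m7-HLH (3.70 ± 0.52), E(spl)m8-HLH (2.47 ± 0.36) and E(spl)m6-BFM (2.19 ± 0.44) were higher in ISC, klu (-1.16 ± 0.32) was higher in EB and the other 7 did not pass (5 and 1 adjusted over the list alone; adjusted p = 0.00342, and adjusted p = 0.581 with an estimated correlation). The count was 148 without the merged ISC sample, 110 without ISC replicate 3, and 508 and 462 without EB replicate 2 or 3. It was 1811 without the 3 libraries nearest to another type. The 3 hormone genes, GstD2, mt:tRNA:Gly-TCC, Mur29B and Srg3 lost their call in at least 1 of the fits without 1 sample. In regions 1159 genes were higher in ISC and 2449 lower, so that 32.1% were higher, and 55.3% after quantile normalization. There 6 of 11 progenitor markers were higher in ISC and 5 did not pass (7 adjusted over the list alone; adjusted p = 1.58e-05, and adjusted p = 0.581 with an estimated correlation), led by mira (2.77 ± 0.19) and Delta (2.75 ± 0.26). Of 30 cell cycle genes 12 were higher and 18 did not pass (12 adjusted over the list alone; adjusted p = 2.92e-05, and adjusted p = 0.681 with an estimated correlation), led by Incenp (1.86 ± 0.29) and Cdk1 (1.76 ± 0.36). Of 9 enterocyte markers 6 were lower and 3 did not pass (1 higher and 6 lower adjusted over the list alone; adjusted p = 0.00569, and adjusted p = 0.581 with an estimated correlation), led by the septate junction gene Tsp2A (-3.21 ± 0.31).

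Enterocytes of the whole midgut held 760 higher and 149 lower genes, among them digestive, acid-pump and metal-handling genes that were also higher in EE. The highest were Jon99Ciii (FBgn0003357; 2828 ± 1290 RPKM, n = 2; 6.49 ± 1.37, adjusted p = 0.0092), the peptidoglycan amidase PGRP-SC2 (6.13 ± 0.95), Jon99Fii (5.92 ± 0.84), the proton pump subunit Vha100-4 (5.88 ± 1.17), the alkaline phosphatase Alp9 (5.70 ± 0.94), the maltase Mal-A7 (5.61 ± 0.97), the metallothionein MtnC (5.43 ± 0.93) and Jon99Fi (5.37 ± 0.78). The lowest were GstE2 (-2.84 ± 0.46), scramb2 (-2.40 ± 0.63) and pch2 (-2.21 ± 0.57). Of 40 digestive enzymes 32 were higher and 8 did not pass (36 adjusted over the list alone; adjusted p = 1.19e-19, and adjusted p = 0.581 with an estimated correlation). Of 22 copper cell and acid genes 17 were higher and 5 did not pass (18 higher and 1 lower adjusted over the list alone; adjusted p = 6.19e-12, and adjusted p = 0.581 with an estimated correlation), among them the homeobox gene lab (3.08 ± 0.41). Of 9 enterocyte markers 5 were higher and 4 did not pass (6 adjusted over the list alone; adjusted p = 7.51e-05, and adjusted p = 0.581 with an estimated correlation), led by mex1 (3.41 ± 0.53) and mesh (2.75 ± 0.50). Of 16 metal handling genes 7 were higher and 9 did not pass (9 higher and 1 lower adjusted over the list alone; adjusted p = 0.00174, and adjusted p = 0.581 with an estimated correlation), led by MtnC, MtnD (4.85 ± 0.72) and MtnB (2.82 ± 0.73). Higher genes made up 83.6% of the calls and 67.5% after quantile normalization. The count was 231 without EC replicate 1, and 48 without EC replicate 2. It was 1398 and 1508 without VM replicate 1 or 2 and 1486 without the 3 libraries nearest to another type. Without EC replicate 2 each of the 11 named genes lost its call. In regions 2261 genes were higher and 1382 lower in EC (62.1% higher, 43.3% after quantile normalization and 72.6% with voom). There 24 of 40 digestive enzymes were higher, 2 lower and 14 did not pass (26 and 3 adjusted over the list alone; adjusted p = 0.0013, and adjusted p = 0.746 with an estimated correlation), led by Jon99Cii (3.79 ± 0.86). Among 9 enterocyte markers 2, nub (1.13 ± 0.24) and mex1 (1.02 ± 0.20), were higher and 7 did not pass (2 adjusted over the list alone; adjusted p = 0.397, and adjusted p = 0.852 with an estimated correlation). Progenitor markers were higher too, 7 of 11 with 4 that did not pass (7 adjusted over the list alone; adjusted p = 0.0479, and adjusted p = 0.746 with an estimated correlation). Ribosome biogenesis genes were higher in 13 of 19 cases, and 6 did not pass (13 adjusted over the list alone; adjusted p = 0.00183, and adjusted p = 0.646 with an estimated correlation). The whole-midgut and regional lists shared 339 higher genes against 186.1 for independent lists.

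Enteroendocrine cells of the whole midgut held 999 higher and 644 lower genes. The highest were the lysozymes LysB (FBgn0004425; 1248 ± 338 RPKM, n = 2, against 0.531 to 51.3 in the other types; 7.74 ± 0.99, adjusted p = 0.000203), LysC (7.74 ± 0.85) and LysE (7.55 ± 0.95), the hormone genes AstA (6.98 ± 1.27) and AstC (6.24 ± 1.55), the proteases Jon99Cii (6.61 ± 1.05) and Jon74E (6.39 ± 1.32) and the metallothionein MtnB (6.59 ± 0.73). The lowest were the common transgene marker w, or white (-4.95 ± 0.34), E(spl)m3-HLH (-4.65 ± 0.54) and E(spl)malpha-BFM (-4.56 ± 0.69). Of 12 peptide hormones 9 were higher and 3 did not pass (10 adjusted over the list alone; adjusted p = 3.45e-06, and adjusted p = 0.581 with an estimated correlation). Of 15 neuroendocrine machinery genes 9 were higher and 6 did not pass (10 adjusted over the list alone; adjusted p = 6.22e-07, and adjusted p = 0.581 with an estimated correlation), led by the prohormone convertase amon (4.89 ± 0.55) and IA-2 (4.33 ± 0.85). Of 7 lysozymes 4 were higher and 3 did not pass (4 adjusted over the list alone; adjusted p = 0.00862, and adjusted p = 0.589 with an estimated correlation). Digestive enzymes were higher too, 32 of 40 with 8 that did not pass (34 higher and 1 lower adjusted over the list alone; adjusted p = 1.8e-17, and adjusted p = 0.581 with an estimated correlation). Of 22 copper cell and acid genes 10 were higher and 12 did not pass (12 adjusted over the list alone; adjusted p = 5.58e-06, and adjusted p = 0.581 with an estimated correlation). Metal handling genes were higher in 7 of 16 cases, and 9 did not pass (7 adjusted over the list alone; adjusted p = 0.000208, and adjusted p = 0.581 with an estimated correlation). The enzymes' summed level was 58530 and 73560 RPKM in the 2 EE libraries and 36480 and 52870 in the 2 EC libraries. Of 11 Notch target genes 5 were lower and 6 did not pass (6 lower adjusted over the list alone; adjusted p = 0.00172, and adjusted p = 0.581 with an estimated correlation). The count was 400 and 411 without EE replicate 1 or 2 and 2626 without VM replicate 2. AstA, Jon74E and AstC lost their call without an EE replicate.

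In the regional EE libraries, sorted with another marker, 3341 genes were higher and 2581 lower (56.4% higher, and 43.1% after quantile normalization). Of 12 peptide hormones 11 were higher and 1 did not pass (11 adjusted over the list alone; adjusted p = 3.72e-09, and adjusted p = 0.581 with an estimated correlation), led by AstC (9.66 ± 0.43), Orcokinin (9.64 ± 0.55), CCHa2 (9.37 ± 0.26) and Tk (9.28 ± 0.47). All 16 tested neuroendocrine machinery genes were higher (16 adjusted over the list alone; adjusted p = 6.89e-11, and adjusted p = 0.581 with an estimated correlation), led by the convertase chaperone 7B2 (8.34 ± 0.35). Of 6 enteroendocrine regulators 5 were higher and 1 lower (5 and 1 adjusted over the list alone; adjusted p = 0.00486, and adjusted p = 0.581 with an estimated correlation), led by tap (2.75 ± 0.31). Of 8 neuronal markers 7 were higher and 1 lower (7 and 1 adjusted over the list alone; adjusted p = 0.000786, and adjusted p = 0.581 with an estimated correlation), led by nSyb (2.85 ± 0.17) and Syt1 (2.33 ± 0.14). Of 15 heat shock genes 14 were higher and 1 lower (14 and 1 adjusted over the list alone; adjusted p = 0.00486, and adjusted p = 0.646 with an estimated correlation), led by Hsp68, Hsp67Ba (2.09 ± 0.36) and DnaJ-1 (2.04 ± 0.21). The whole-midgut and regional EE lists shared 526 higher genes against 338.6 for independent lists, while 142 whole-midgut higher genes were lower in regions.

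Muscle genes hardly set the whole-midgut VM libraries apart. In the whole midgut 79 genes were higher and 137 lower. The highest were GILT2 (FBgn0039099; 177 ± 32.4 RPKM, n = 2; 4.83 ± 0.53, adjusted p = 0.00143), Nepl21 (3.07 ± 0.67), the germline factor piwi (2.55 ± 0.51), Corp (2.43 ± 0.30), l(1)G0289 (2.23 ± 0.39), sll (2.06 ± 0.48), shf (2.02 ± 0.38) and FucTA (adjusted p = 0.00253). The lowest were MtnB (-4.63 ± 0.73), Ugt304A1 (-3.30 ± 0.42) and MtnA (-3.11 ± 0.73). Of 20 muscle genes 1 was higher, the myosin light chain Mlc2 (1.23 ± 0.22), and 19 did not pass (2 higher and 1 lower adjusted over the list alone; adjusted p = 0.087, and adjusted p = 0.681 with an estimated correlation). On the deposited values 3 were higher and 6 lower. No gene of 7 extracellular matrix genes passed limma or was called when adjusted over the list alone (adjusted p = 0.811, and adjusted p = 0.966 with an estimated correlation). The count was 101 and 104 without the merged ISC sample or ISC replicate 3, 143 without EB replicate 2, 131 and 130 without EC replicate 1 or 2, and 143 without EE replicate 1. It was 1077 and 751 without VM replicate 1 or 2. Nepl21, sll, shf and MtnA lost their call in at least 1 of these fits. Higher genes made up 36.6% of the calls and 83.9% with voom. In regions 2080 genes were higher and 3467 lower in VM. Of 17 muscle genes 11 were higher, 2 lower and 4 did not pass (11 and 2 adjusted over the list alone; adjusted p = 0.000111, and adjusted p = 0.581 with an estimated correlation), led by Mlc2 (1.85 ± 0.18), Mp20 (1.71 ± 0.19) and TpnC25D (1.23 ± 0.11). Of 40 digestive enzymes 27 were higher and 13 did not pass (27 adjusted over the list alone; adjusted p = 1.33e-08, and adjusted p = 0.589 with an estimated correlation), led by Jon25Bi (3.61 ± 0.56) and Mal-A7 (3.40 ± 0.43). All 10 regional VM libraries correlated better with EC of their region than with VM elsewhere. The whole-midgut and regional VM lists shared 16 higher genes (15.22 for independent lists) and 30 lower (50.9), with 17 and 52 opposite in regions. At 2-fold or more they shared 7 (4.7) and 17 (4.5), with 2 and 22 opposite.

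Each EC region was compared with the mean of the other 4 to find how the absorptive epithelium varies along the gut. R1 held 624 higher and 93 lower genes (87.0% higher, and 66.8% after quantile normalization). The highest were EbpIII (FBgn0011695; 1935 ± 1460 RPKM, n = 2, against 0.927 to 11.3 in the other regions; 9.04 ± 0.65, adjusted p = 7.02e-12), the juvenile hormone-binding gene Jhbp1 (8.78 ± 0.49), Jon74E (8.65 ± 1.20), takeout, to (8.56 ± 0.69), the mucin Muc68D (7.76 ± 0.29) and Phk-3 (7.59 ± 0.79). Of 15 antimicrobial peptides 6 were higher in R1 and 9 did not pass (8 adjusted over the list alone; adjusted p = 0.00256, and adjusted p = 0.903 with an estimated correlation), led by DptA (4.57 ± 1.0) and AttD (3.67 ± 0.76). R2 held 49 higher and 51 lower genes. The highest were Mal-A7 (5.05 ± 0.96), the aspartic protease Bace (4.71 ± 1.10), the alkaline phosphatases Alp10 (4.50 ± 0.75) and Alp9 (4.36 ± 0.85), Sfp53D (2.18 ± 0.22) and mira (adjusted p = 0.0174). R3, the region of the acid-secreting copper cells, held 338 higher and 524 lower genes (39.2% higher, and 60.6% after quantile normalization). It was led by Vha100-4 (1157 ± 707 RPKM, n = 2, against 0.573 to 44.8; 7.81 ± 1.53, adjusted p = 0.00145), Pgcl (5.96 ± 0.80), MtnB (5.36 ± 0.82), Jon65Ai (5.26 ± 1.69), the proton channel gene OtopLb (4.97 ± 1.00) and Tsp42Ec (4.91 ± 0.77). Of 23 copper cell and acid genes 15 were higher in R3, 2 lower and 6 did not pass (15 and 2 adjusted over the list alone; adjusted p = 1.13e-12, and adjusted p = 0.061 with an estimated correlation). Of 16 metal handling genes 6 were higher and 10 did not pass (8 higher and 1 lower adjusted over the list alone; adjusted p = 0.00108, and adjusted p = 0.226 with an estimated correlation). R4 held 213 higher and 281 lower genes (43.1% higher, 54.4% after quantile normalization and 60.8% with voom). Its highest genes were Jon99Fii (6.10 ± 1.35), Jon99Fi (6.04 ± 1.57), lambdaTry (4.67 ± 0.71), Jon44E (4.30 ± 0.99), the sterol carrier Npc2d (4.25 ± 0.70) and Ser8 (4.17 ± 0.74). R5 held 241 higher and 133 lower genes. Leading them were Acbp3 (6.62 ± 1.06), zetaTry (5.97 ± 1.14), Try29F (5.41 ± 0.57), iotaTry (5.08 ± 1.01), the cytochrome P450 Cyp4ad1 (4.73 ± 0.46) and the chitinase Cht9 (3.47 ± 0.71). With voom the higher share was 94.3% in R2, 49.4% in R3 and 84.2% in R5.

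Digestive enzymes differed by region as single genes more than as a group. Of 40 tested, 9 were higher and 2 lower in R1, 5 and 0 in R2, 2 and 9 in R3, 6 and 0 in R4 and 6 and 8 in R5. Adjusted over the list alone the numbers were 11 and 7, 9 and 7, 3 and 12, 6 and 0, and 8 and 12. The list passed in R5 (adjusted p = 0.0498, and adjusted p = 0.903 with an estimated correlation) and not in the other regions. Of 22 transcription factors with known regional patterns 3 were higher and 2 lower in R1, 1 and 2 in R2, 3 and 4 in R3, 1 and 2 in R4 and 3 and 2 in R5 (5 and 2, 2 and 2, 3 and 4, 2 and 2, and 4 and 2 adjusted over the list alone), and the list, tested for a shift in 1 direction, passed in no region (lowest adjusted p = 0.156 by camera, in R2, and adjusted p = 0.903 with an estimated correlation). The homeobox gene lab (4.44 ± 0.55) and Ptx1 (2.58 ± 0.30) were higher in R3, where drm (-2.45 ± 0.23) and odd (-2.41 ± 0.37) were lower. The caudal gene, cad, was higher in R4 and R5 (1.86 ± 0.26) and lower in R1 (-1.47 ± 0.26) and R2. The gene drm was higher in R1 (2.23 ± 0.23) and R5 (3.29 ± 0.23). The regional counts moved with single libraries. R1 gave 349 genes without R1 replicate 1, and R2 gave 23 and 35 without R2 replicate 1 or 2 and 153 without R1 replicate 2. R3 gave 77 without R3 replicate 1, R4 gave 855 and 177 without R4 replicate 1 or 2, and R5 gave 116 without R5 replicate 1. Bace, Mal-A7, Alp9, Alp10, mira, Vha100-4, Jon65Ai, OtopLb, Jon99Fii, Jon99Fi, Jon44E, zetaTry, iotaTry and Cht9 lost their call in at least 1 fit without 1 library. The other 16 of the 30 genes named for EC regions passed in each. Without the 4 regional libraries nearest to another type the 5 counts were 1076, 222, 1682, 976 and 682. With a replicate block within each type R3 gave 1527, R4 1125 and R5 673.

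**Figure D2:**
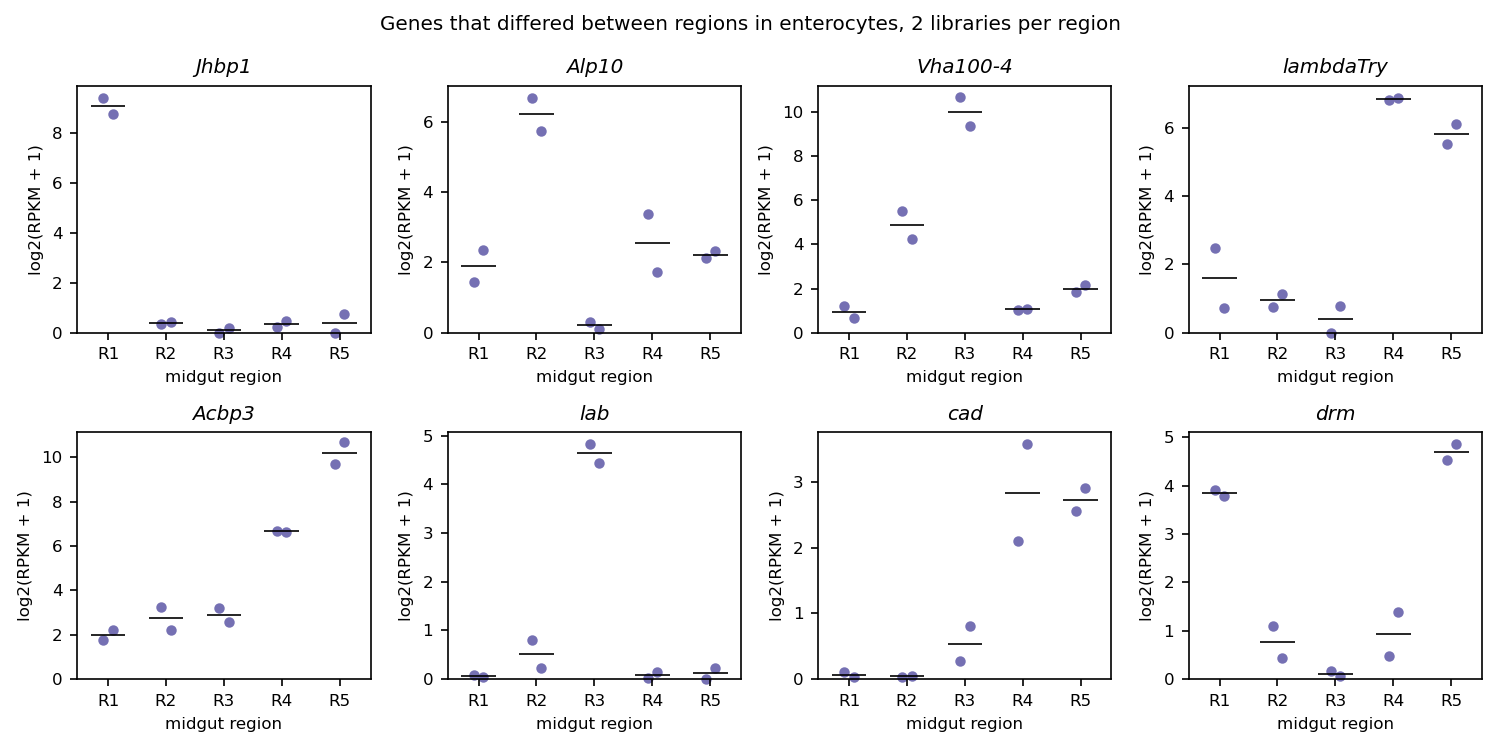
Levels of 8 genes in enterocytes of regions R1 to R5, as log2(RPKM + 1), with 2 libraries per region as points. Jhbp1 is high in R1, Alp10 in R2, Vha100-4 and lab in R3, lambdaTry in R4, Acbp3 in R5, cad in R4 and R5 and drm in R1 and R5.

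Tests across the 5 regions within each type called 1660 genes in ISC, 645 in EB, 1596 in EC, 3513 in EE and 3943 in VM. Without ISC R1 replicate 2, R3 replicate 1 or R3 replicate 2 the ISC count was 766, 973 or 982, and without EC R3 replicate 1 the EC count was 1033. Some of the genes named for EC regions were also higher in the same region of another type. RNA of other cells was not excluded (VM R4 replicate 2 was nearest to EB of R4). Vha100-4 (6.02 ± 1.53) and MtnB (7.19 ± 0.82) were higher in ISC of R3, lab and Pgcl (3.19 ± 0.55 and 4.96 ± 0.80) in EB of R3, lab (4.19 ± 0.55) in EE of R3, and lambdaTry in EB (3.53 ± 0.71) and VM (5.99 ± 0.71) of R4. Acbp3 (3.99 ± 1.06) and drm (3.35 ± 0.23) were higher in EB of R5. Other genes were named for these types alone, with shared regional genes not counted. In R1, to, which is also named for EC, and Jhbp14 were higher in EB (9.33 ± 0.69 and 9.59 ± 0.58) and VM (8.93 ± 0.69 and 10.31 ± 0.58). There, whe and lcs were higher in ISC (12.77 ± 2.21 and 12.17 ± 1.37) and EE (13.12 ± 2.21 and 12.68 ± 1.37). EE of R2 held more CCHa2 (8411 ± 125 RPKM, n = 2; 3.41 ± 0.57) and the sulfonylurea receptor gene Sur (3.40 ± 0.17). EE of R4 held more Mip (5.24 ± 0.53) and EE of R5 more AstA (9.65 ± 0.99) and IM33 (8.28 ± 0.72). In ISC, Tk (4.87 ± 1.05) was higher in R5 and AstC (4.82 ± 0.96) in R4. The calls of Vha100-4 in ISC of R3, lab and Pgcl in EB of R3, Acbp3 in EB of R5, whe in ISC of R1 and AstC in ISC of R4 were lost in at least 1 fit without 1 library.

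Infection was tested within each type, to ask how the cells of the gut respond to an ingested pathogen. In ISC 1223 genes rose and 193 fell, and 2046 and 506 in a fit of the ISC libraries alone. The largest rises were those of Acbp5 (767 ± 433 RPKM, n = 2, against 9.36 and 10.2 in uninfected ISC; 6.03 ± 0.74, adjusted p = 0.000389), the eggshell genes Vm34Ca (43.0 ± 24.3 RPKM, listed at 0 in uninfected ISC), Vm26Ab (4.80 ± 0.36) and Vm26Aa (4.68 ± 0.34), the juvenile hormone epoxide hydrolase Jheh3 (4.07 ± 0.57), Npc2e (4.04 ± 0.98), Acbp6 (3.95 ± 1.04) and the RNA polymerase subunit Polr2K (3.94 ± 0.49). The largest falls were those of lncRNA:CR40469 (-4.18 ± 0.76), Ugt35C1 (-4.09 ± 0.86), MtnA (-3.93 ± 0.93), mt:ND2 (-3.90 ± 1.01), Hsp27 (-3.80 ± 1.18), mt:tRNA:Phe-GAA and mt:tRNA:Trp-TCA, both listed at 0 after infection, and mir-2b-2 (-3.24 ± 0.42). Of 31 cell cycle genes 8 rose and 23 did not pass (14 rose and 1 fell adjusted over the list alone; adjusted p = 0.00737, and adjusted p = 0.927 with an estimated correlation), led by the ribonucleotide reductase genes RnrS (3.01 ± 0.88) and RnrL (2.72 ± 0.61), but after quantile normalization 0 rose and 1 fell. Of 5 ovary and germline markers 3 rose, the Vm genes, and 2 did not pass (3 adjusted over the list alone; adjusted p = 0.000523, and adjusted p = 0.398 with an estimated correlation). Of 6 fat body markers 3 rose, the yolk protein genes Yp1, Yp2 and Yp3, and 3 did not pass (3 adjusted over the list alone; adjusted p = 0.117, and adjusted p = 0.696 with an estimated correlation). Of 10 JAK-STAT pathway genes the cytokine upd3 (3.20 ± 0.91) and the receptor dome (1.54 ± 0.39) rose and 8 did not pass (2 adjusted over the list alone; adjusted p = 0.838, and adjusted p = 0.976 with an estimated correlation). Of 12 EGFR pathway genes rho (-1.82 ± 0.34) and vn (-1.34 ± 0.23) fell and 10 did not pass (2 adjusted over the list alone; adjusted p = 0.00259, and adjusted p = 0.398 with an estimated correlation). None of 17 antimicrobial peptides passed limma or was called when adjusted over the list alone (adjusted p = 0.0624, and adjusted p = 0.927 with an estimated correlation). Rises made up 86.4% of the calls and 50.1% after quantile normalization, which moved the median log2 fold change of all genes by -0.275. The count was 475 without the merged ISC sample, 343 without uninfected ISC replicate 3 and 490 without infected ISC replicate 2. Npc2e, Acbp6, Ugt35C1, MtnA, mt:ND2, Hsp27 and mt:tRNA:Phe-GAA lost their call in at least 1 fit without 1 sample.

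In EB 1964 genes rose and 1499 fell, and contractile genes were prominent among the rises. The largest were those of mt:tRNA:Lys-CTT (827 ± 4.70 RPKM, n = 2, listed at 0 in uninfected EB), AANATL4 (8.72 ± 0.67), the muscle protein gene Mp20 (558 ± 82.0 RPKM, n = 2, against at most 1.37 in uninfected EB, n = 3; 8.60 ± 0.49, adjusted p = 1e-08), Mlc2 (8.04 ± 0.26), Arc1 (7.90 ± 1.15), the troponin gene TpnC73F (7.53 ± 0.68), Acbp6 (7.53 ± 0.95) and GstD5 (7.43 ± 1.11). The largest falls were those of Dtg (-6.55 ± 0.93), E(spl)m3-HLH (-6.53 ± 0.63), E(spl)malpha-BFM (-6.20 ± 0.80), Erasp (-6.04 ± 1.07), Tmhs (-5.48 ± 0.56), mt:ND6 (-5.47 ± 1.88), Hsp68 (-5.36 ± 1.22) and rau (-5.18 ± 0.53). Of 20 muscle genes 16 rose, 1 fell and 3 did not pass (16 and 2 adjusted over the list alone; adjusted p = 1.59e-13, and adjusted p = 0.184 with an estimated correlation). Digestive enzymes rose in 24 of 40 cases, and 16 did not pass (29 adjusted over the list alone; adjusted p = 2.33e-05, and adjusted p = 0.831 with an estimated correlation), led by Jon65Ai (7.13 ± 0.98). Of 33 detoxification genes 19 rose, 2 fell and 12 did not pass (21 and 2 adjusted over the list alone; adjusted p = 0.00118, and adjusted p = 0.777 with an estimated correlation), led by GstD5 and MtnB (7.32 ± 0.85). All 6 fat body markers rose (6 adjusted over the list alone; adjusted p = 0.000302, and adjusted p = 0.334 with an estimated correlation), led by Yp1 (5.71 ± 0.61). Of 17 antimicrobial peptides 7 rose and 10 did not pass (7 adjusted over the list alone; adjusted p = 0.0425, and adjusted p = 0.927 with an estimated correlation), led by Drsl3 (5.82 ± 1.1). Of 11 Notch target genes 4 fell, 1 rose and 6 did not pass (4 and 1 adjusted over the list alone; adjusted p = 0.127, and adjusted p = 0.865 with an estimated correlation). Of 31 cell cycle genes 12 fell, 1 rose and 18 did not pass (12 and 1 adjusted over the list alone; adjusted p = 0.00118, and adjusted p = 0.901 with an estimated correlation). Of 15 heat shock genes 10 fell, 1 rose and 4 did not pass (12 and 2 adjusted over the list alone; adjusted p = 0.0115, and adjusted p = 0.865 with an estimated correlation). Su(H) stood at 0.0769 ± 0.0595 RPKM after infection (n = 2) and at 1.78 ± 0.311 without (n = 3). Rises made up 56.7% of the calls and 44.5% after quantile normalization, which moved the median by -0.169. The call of mt:ND6 was lost in 4 fits without 1 library, namely without uninfected EB replicate 1 or 2 or infected EB replicate 1 or 2.

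In EC 2142 genes rose and 518 fell, and 758 and 85 in a fit of the EC libraries alone. The largest rises were those of the tRNAs mt:tRNA:Lys-CTT and mt:tRNA:Tyr-GTA, both listed at 0 in uninfected EC, GstD2 (3281 ± 572 RPKM, n = 2, against 32.8 and 103; 5.78 ± 1.21, adjusted p = 0.00254), LysC (5.33 ± 1.09), the stress-induced TotC (4.92 ± 1.52), the replication clamp gene PCNA (4.90 ± 0.75), nAChRbeta3 (4.83 ± 0.79) and the chaperonin subunit CCT5 (4.82 ± 0.60). The largest falls were those of the mitochondrial genes mt:ND6 (-9.66 ± 2.06), mt:ND4L (-6.44 ± 0.80), mt:ND3 (-5.29 ± 1.28) and mt:ND2 (-5.23 ± 1.01), and of Diedel3 (-6.00 ± 1.84), Alp9 (-5.81 ± 1.20), dmGlut (-5.65 ± 1.04) and Ctns (-5.19 ± 1.12). Of 31 cell cycle genes 16 rose and 15 did not pass (19 adjusted over the list alone; adjusted p = 0.000603, and adjusted p = 0.901 with an estimated correlation), led by PCNA, RnrL (4.20 ± 0.61) and aurB (4.01 ± 0.82). The stem cell marker Delta stood at 2.82 and 6.53 RPKM in infected EC and at 0.814 and 1.01 in uninfected EC. Of 19 ribosome biogenesis genes 13 rose and 6 did not pass (14 adjusted over the list alone; adjusted p = 0.00051, and adjusted p = 0.673 with an estimated correlation), led by Fib (3.79 ± 0.56). Of 22 copper cell and acid genes 12 fell and 10 did not pass (12 adjusted over the list alone; adjusted p = 9.59e-10, and adjusted p = 0.398 with an estimated correlation), led by lab (-2.62 ± 0.52) and VhaSFD (-2.45 ± 0.50). Of 40 digestive enzymes 5 fell and 35 did not pass (0 adjusted over the list alone; adjusted p = 1.43e-06, and adjusted p = 0.777 with an estimated correlation). Without infected EC replicate 2, the library nearest to infected ISC (r 0.9211, against 0.8837 with its own replicate), 4 rose and 0 fell. Of 19 Imd pathway genes 6 rose, 1 fell and 12 did not pass (8 and 1 adjusted over the list alone; adjusted p = 0.657, and adjusted p = 0.958 with an estimated correlation), led by the NF-kappaB factor Rel (2.94 ± 0.57). None of 17 antimicrobial peptides passed limma or was called when adjusted over the list alone (adjusted p = 0.621, and adjusted p = 0.976 with an estimated correlation). Rises made up 80.5% of the calls, 56.5% after quantile normalization, which moved the median by -0.274, and 65.6% with voom. The count was 1473 without uninfected EC replicate 1 and 1716 without infected EC replicate 2. The 2 tRNAs, TotC, Diedel3 and mt:ND3 lost their call in at least 1 fit without 1 library.

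In EE 1003 genes rose and 234 fell, and 285 and 139 in a fit of the EE libraries alone. The largest rises were those of the immune-induced edin (5.05 ± 1.42), CCHa2 (7097 ± 5210 RPKM, n = 3, against 110 and 301 in uninfected EE; 4.72 ± 1.22, adjusted p = 0.0219), Had2 (4.51 ± 0.96), Mtkl (4.14 ± 1.16), mthl2 (4.13 ± 1.18), the matrix protein gene SPARC (4.04 ± 1.13), lectin-24Db (4.01 ± 1.10) and the immune catalase Irc (3.91 ± 1.16). The largest falls were those of whe (-6.95 ± 1.96), Diedel3 (-6.36 ± 1.68), lcs (-6.28 ± 1.83), thetaTry (-5.89 ± 1.33), yip7 (-5.15 ± 1.35), hiro (adjusted p = 0.0296), Alp9 (-4.99 ± 1.10) and Bace (-4.95 ± 1.45). Digestive enzymes fell in 15 of 40 cases and rose in 1, and 24 did not pass (22 and 1 adjusted over the list alone; adjusted p = 1.34e-20, and adjusted p = 0.398 with an estimated correlation). Their summed level was 15910, 2634 and 2207 RPKM in the 3 infected libraries against 58530 and 73560. Of 15 neuroendocrine machinery genes 13 rose and 2 did not pass (15 adjusted over the list alone; adjusted p = 9.11e-10, and adjusted p = 0.398 with an estimated correlation), led by Pal2 (3.37 ± 0.65), 7B2 (3.09 ± 0.67) and Rab3 (2.96 ± 0.75). Of 12 peptide hormones 5 rose and 7 did not pass (7 adjusted over the list alone; adjusted p = 0.0107, and adjusted p = 0.777 with an estimated correlation), led by CCHa2 and sNPF (3.88 ± 0.78). Of 7 haemocyte markers 1 rose, the phagocytosis receptor NimC1 (3.88 ± 1.1), and 6 did not pass, with a median over the list of 2.86 (7 adjusted over the list alone; adjusted p = 0.0231, and adjusted p = 0.865 with an estimated correlation). Of 7 extracellular matrix genes, several of which blood cells also make, 4 rose and 3 did not pass (5 adjusted over the list alone; adjusted p = 0.131, and adjusted p = 0.802 with an estimated correlation), and 0 rose after quantile normalization or with voom. Rises made up 81.1% of the calls and 50.3% after quantile normalization, which moved the median by -0.38. The count was 175 and 613 without uninfected EE replicate 1 or 2, and 693 and 532 without infected EE replicate 2 or 3. It was 2212 without the 3 libraries nearest to another type. Each of the 16 named genes lost its call without uninfected EE replicate 1.

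**Figure D3:**
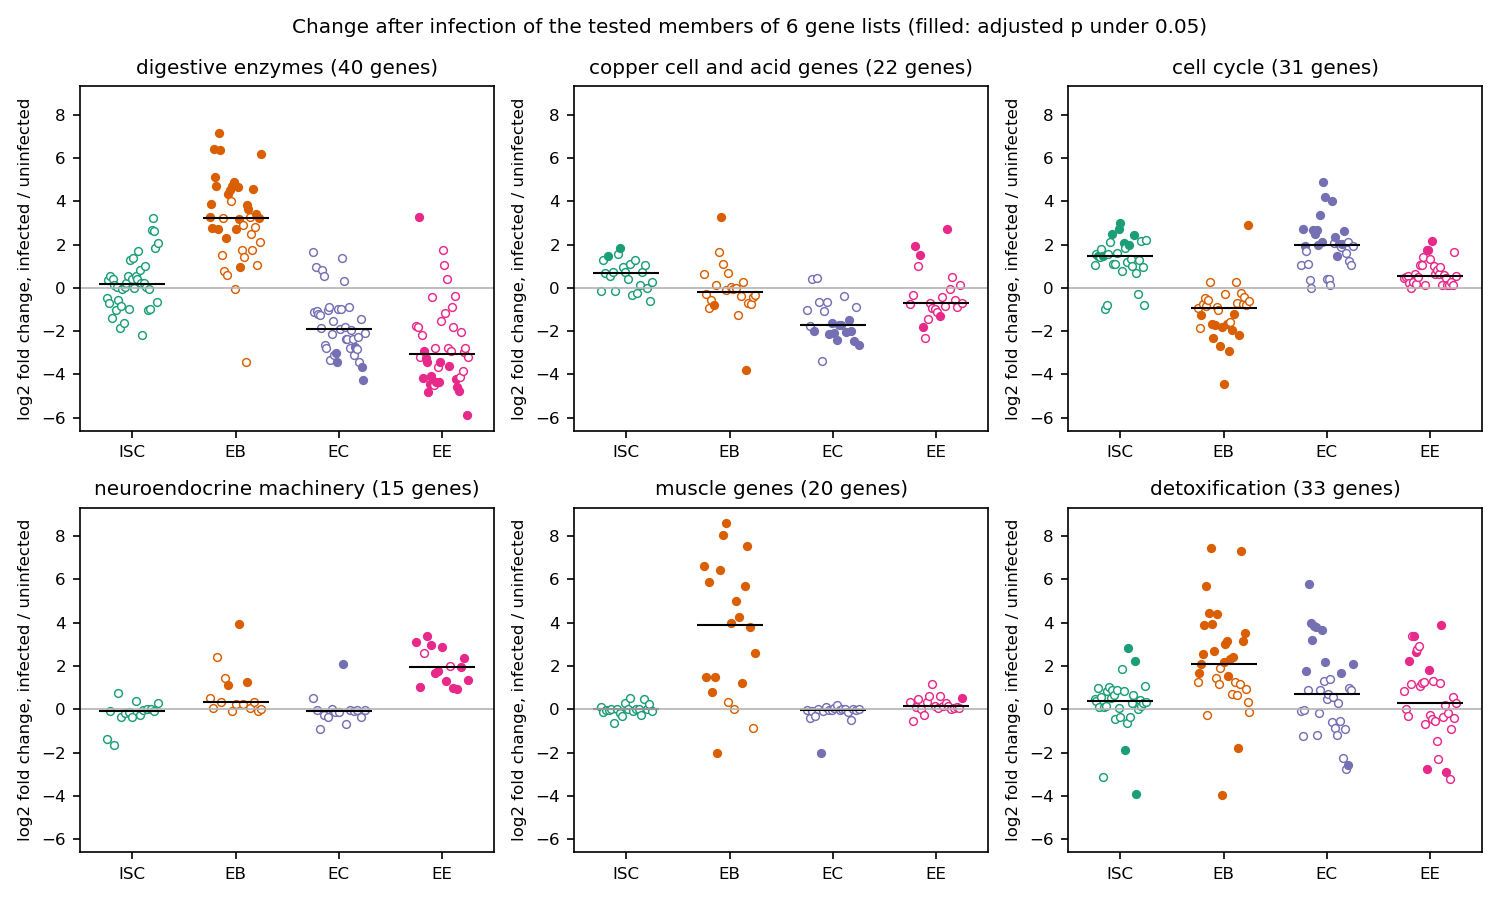
Log2 fold changes (infected minus uninfected, log2(RPKM + 1) scale) of the tested members of 6 gene lists in ISC, EB, EC and EE of the whole midgut. Points are genes, filled where the adjusted p is below 0.05, and lines are list medians. Called members are 24 of 40 digestive enzymes above 0 in EB, 15 below 0 in EE and 5 below 0 in EC, 16 of 20 muscle genes above 0 in EB, 16 of 31 cell cycle genes above 0 in EC and 8 in ISC (0 after quantile normalization), and 13 of 15 neuroendocrine genes above 0 in EE. None of these lists passed with an estimated correlation.

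Whether the response differed between types was tested directly, and 5230 genes differed in their change with infection among ISC, EB, EC and EE. Without EB, whose infected libraries are doubted, the number was 1895. ISC and EC shared 501 rises where independent lists would share 288, but infected EC replicate 2 is nearest to infected ISC and the excess of rises in both types shrank after quantile normalization. ISC and EE shared 111 rises against 135 and EC and EE shared 210 against 237, while EC and EE shared 71 falls against 13.3. ISC and EB shared 113 rises against 264, and EB and EC shared 282 against 463. No control library is shared between types. Blos2, the translation factor eIF5B, Ipp, kraken and lncRNA:CR43264, chosen after their values were seen, rose in all 4 types, where independent lists would share 6.89 genes, and 0 genes fell in all 4 by limma, against 0.0468.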

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

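The tests on digestive enzymes in EE, on infected EB and on regional VM were chosen after the results were seen, those on EE enzymes, muscle genes, dilution (at 1 of several cutoffs seen) and VM in another form after a first one had been seen, while the counts over other splits of the samples were planned.

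The response to infection differed between cell types at 5230 genes by an F-test of the difference, and at 1895 genes without EB. With both changes past the threshold, 403 genes rose in one and fell in the other of ISC and EB (1.65 times the number for independent lists of these sizes), 92 of ISC and EC (0.798), 34 of ISC and EE (0.644), 553 of EB and EC (1.19), 285 of EB and EE (1.32) and 32 of EC and EE (0.285). No group held 4 or more samples, so that no test for a single sample far from its group was made.

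Digestive enzymes summed higher in both uninfected whole-midgut EE libraries than in EC, and far lower in infected EE. With 2 samples each, a limma test of EE against EC cannot decide whether RNA of enterocytes is the source. Adjusted over the list 0 of 40 enzymes were higher and 1 lower (2 higher at an unadjusted p under 0.05). RNA of the EC sorted here would not alone give higher sums, but other enterocyte genes were high too. Of 9 enterocyte markers 4 were higher and 5 did not pass (4 adjusted over the list alone; adjusted p = 0.000887, and adjusted p = 0.581 with an estimated correlation), and 10 of 22 copper cell and acid genes were higher. Peptide hormones summed to 7266 and 15890 RPKM in the uninfected EE libraries and to 57210 to 74870 in infected EE. Of 40 enzymes 14 had both uninfected EE libraries above both EC libraries, where 6.67 would by chance, and 10 had both below. Enterocytes of another regional makeup and an effect of infection, not tested apart from such RNA, stay open.

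In infected EB 16 of 20 muscle genes rose, while 4 of 11 Notch target genes fell and 1 rose, a list that did not pass (adjusted p = 0.127). RNA of muscle cells like the VM sorted here is argued against as the source of the first, since the lowest infected EB sum of muscle genes (1663 RPKM) was 4.99 times the highest sum of a VM library (333), but RNA of purer muscle cells was not tested and stays open. Dilution by other cells cannot be told apart from a loss of these 4 genes in EB, since genes at 10 RPKM or more in EB and at least 4-fold above EC and EE had a median change of -2.53 when picked in the whole midgut (71 genes, picked in libraries that are compared) and of 0.316 when picked in regions (36 genes, 31 of them below 10 in uninfected whole-midgut EB). Libraries of another type under the EB label cannot be told apart from an effect of infection, since infected EB correlated with uninfected EB at 0.667 and with EC and EE at 0.758 and 0.755, all below the 0.879 of the infected EB pair, a bound raised after a lower one, 0.723, had been met. An effect of infection on EB stays open and untested apart from these.

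In regional VM 27 of 40 digestive enzymes were higher than the mean of the other 4 types (adjusted p = 1.33e-08, and adjusted p = 0.589 with an estimated correlation). RNA of epithelial cells in VM stays open. All 10 VM libraries correlated better with EC of their region than with VM elsewhere. For their own types this held for 2 ISC, 1 EB and 2 EE libraries. But VM differed by region (mean r 0.763 to 0.854), and EC elsewhere was not compared. Whether enterocytes like those sorted here are the whole source cannot be told, since 6 enzymes were higher in VM than in EC in a direct test adjusted over the list (7 over all genes), which a mixture would not give, but 2 (4 over all genes, and 9 with 0 lower at an unadjusted p under 0.05) with means over regions as samples. Expression of these enzymes in muscle was not tested apart from such RNA.

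Whether chance could give such counts was examined with other splits of the samples. For EB in the whole midgut 7 of 100 splits gave as many genes as the real one (483, highest other 1437, several times the real count, which points to structure among the samples), so that chance is not excluded. For each of the 6 regional cell type results 1 of 100 splits, the real one, gave as many. This bears on whether types differ at all, not on the count of 1 type. It takes libraries of a region as independent, which same-numbered ones are not in full. ISC gave 6043 (highest other 285), EB 4617 (173) and EC 3643 (394). EE gave 5922 (342), VM 5547 (328) and ISC against EB 3608 (172). The other whole-midgut, infection and EC region results compare groups of under 3 samples, for which no splits were counted.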

How the results depend on the processing

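Chosen after seeing the data were the fits on the deposited values, with voom, without the libraries nearest to another type, without VM or EB, with ISC replicates 1 and 2 separate, with a replicate block within each type and with means of same-numbered regional libraries as samples. Across these and the alternatives fixed in advance no named gene reversed except 2 on the deposited values, sll (-0.0891) and how (-0.82) in whole-midgut VM, where the change of divisor is the alternative itself. Of named genes the call ended for 13 after quantile normalization, 39 with voom, 10 without a filter and 8 with a pseudocount of 0.1. It ended for 33 in fits of the groups compared alone, 8 on the deposited values, 1 without the libraries nearest to another type and 1 without VM. Without 1 library it ended in 264 cases, against 1755 with no change. The 1755 include cases of marker genes that had no call to lose. After quantile normalization and on the deposited values 1 gene each gained a call. With a change of at least 2-fold, 12 of the numbers of genes shared by whole-midgut and regional lists moved by over 1.5 times. Quantile normalization also moved the median log2 fold change of all genes, by 0.18 in regional ISC, -0.105 in EC, -0.139 in EE and 0.125 in ISC against EB, and by -0.113 and 0.168 in EC of R1 and R3. The cause was not tested for the changes below, except that fits of the groups compared alone and fits without libraries use fewer samples.

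Counts of genes that moved by over 1.5 times were as follows. On the deposited values EB gave 2077 genes, EC 1891 and VM 4734. With ISC replicates separate, ISC gave 3242, VM 399 and ISC against EB 1762. With a change of at least 2-fold, regional ISC gave 1261, EB 697, EC 511, EE 1666, VM 937 and ISC against EB 892, and EC of R3 and R4 gave 560 and 253. Without a filter whole-midgut VM gave 372. In fits of the groups compared alone EB gave 928, VM 687, ISC against EB 2857, infected ISC 2552, EC 843 and EE 424, EC of R3, R4 and R5 468, 101 and 245, and the tests across regions 758 in EC, 1958 in EE and 2352 in VM. A pseudocount of 0.1 gave 31 in EC of R2 and 295 in R4. Quantile normalization gave 818 in EB, 373 in VM, 824 in infected ISC and 551 in infected EE. Voom gave 441 in VM, 928 in infected ISC, 297 in infected EE, 35 and 237 in EC of R2 and R4 and 1101 across regions of ISC. Without EB the difference in infection response gave 1895. Without VM, EB gave 1359 and infected EE 1873. Without the libraries nearest to another type ISC gave 3327, EB 1736, EC 1486, ISC against EB 1811, infected EE 2212, EC of R1 to R5 1076, 222, 1682, 976 and 682, and tests across regions 2731 in ISC and 2642 in EC. With an estimated correlation the 130, 39 and 24 list calls became 0, 0 and 0.

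Without 1 library the counts ranged from 469 to 2881 in ISC, 90 to 1460 in EB, 48 to 1508 in EC, 400 to 2626 in EE, 101 to 1077 in VM and 110 to 955 in ISC against EB. For infection they ranged from 343 to 974 in ISC, 2813 to 3125 in EB, 1473 to 2721 in EC, 175 to 1778 in EE and 4509 to 5463 for the difference. For regional types they ranged from 5575 to 6197 in ISC, 4071 to 4872 in EB, 3056 to 4016 in EC, 5566 to 6105 in EE, 4649 to 5857 in VM and 3261 to 3640 in ISC against EB. For EC they ranged from 349 to 797 in R1, 23 to 153 in R2, 77 to 885 in R3, 177 to 855 in R4 and 116 to 506 in R5, and across regions from 766 to 2299 in ISC, 481 to 822 in EB, 1033 to 1942 in EC, 2585 to 4519 in EE and 3171 to 4320 in VM. Where a fit left 1 sample in a group, that sample is assumed to vary like the other groups.

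Samples share replicate numbers across groups, but the labels do not say that a number marks a batch. Deviations from the group means correlated above 0.1 in 3 of 36 pairs of groups in the whole midgut (-0.211 to 0.182, median -0.0124) so that the numbers were not taken as pairs there. In regions they did so in 157 of 300 pairs and lay below -0.1 in 32 (-0.442 to 0.697, median 0.112), most of all within a type, in 10 of 10 pairs in EB (at most 0.553) and EC (0.225 to 0.538). A replicate block within each type gave 1527, 1125 and 673 genes in EC of R3, R4 and R5 and 3257 and 2715 across regions of ISC and EC, left the other 5 counts within 1.5 times and ended the call of 0 of 70 named genes. Means over regions of the same-numbered libraries of a type as samples gave 3525 genes in ISC, 1809 in EB, 907 in EC, 2574 in VM and 1284 in ISC against EB, left EE within 1.5 times and ended the calls of Su(H) and how, with fewer samples in the fit. With a replicate block shared by all types EB gave 252 genes, VM 108 and infected EE 714; the other 24 counts stayed within 1.5 times, and 20 named genes were no longer called. Depth limits the whole midgut more than regions. Genes near 1 RPKM are the least certain. Results planned for the further sorted population were not run, and alternatives planned for counts do not apply to these values.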

Other observations

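The lists here were fixed before the data were examined, while sNPF and ple in R1 were chosen after their values were seen.

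Infected ISC held more transcript of several enterocyte genes. Of 9 enterocyte markers 4 rose and 5 did not pass (4 adjusted over the list alone; adjusted p = 0.0115, and adjusted p = 0.741 with an estimated correlation). They were the smooth septate junction genes mesh (3.45 ± 0.64), Tsp2A (2.81 ± 0.62) and Ssk (2.79 ± 0.61) and the transcription factor nub (2.56 ± 0.80). The growth factor gene Pvf2 fell in infected ISC (-3.02 ± 0.48) and EB (-2.22 ± 0.44). In infected EB, of 10 JAK-STAT pathway genes 5 rose and 5 did not pass (5 adjusted over the list alone; adjusted p = 0.175, and adjusted p = 0.901 with an estimated correlation). The stress genes TotC (4.73 ± 1.4) and TotM (4.49 ± 0.80) led them. Of 11 progenitor markers 6 fell and 5 did not pass (6 adjusted over the list alone; adjusted p = 0.0171, and adjusted p = 0.899 with an estimated correlation), led by Sox21a (-4.08 ± 1.2) and Sox100B (-3.86 ± 1.0). Of 19 ribosome biogenesis genes 11 fell, 1 rose and 7 did not pass (11 and 1 adjusted over the list alone; adjusted p = 0.000449, and adjusted p = 0.673 with an estimated correlation), led by Nnp-1 (-3.12 ± 0.55). Some markers of neighbouring tissues rose in infected EB, though neither list passed. Of 3 tracheal markers Gasp (2.74 ± 0.69) and stumps (2.06 ± 0.27) rose and 1 did not pass (2 adjusted over the list alone; adjusted p = 0.119, and adjusted p = 0.777 with an estimated correlation). Of 7 Malpighian tubule markers 3 rose and 4 did not pass (3 adjusted over the list alone; adjusted p = 0.131, and adjusted p = 0.865 with an estimated correlation), led by the urate oxidase gene Uro (4.68 ± 0.65).

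In infected EE the amidase genes PGRP-SC1b (-4.61 ± 0.63) and PGRP-SC1a (-3.95 ± 0.58) fell and PGRP-LB (1.74 ± 0.47) rose among 19 Imd pathway genes, and 16 did not pass (3 fell and 1 rose adjusted over the list alone; adjusted p = 0.544, and adjusted p = 0.95 with an estimated correlation). Of 17 antimicrobial peptides CecA2 rose (3.52 ± 1.0) and 16 did not pass (6 adjusted over the list alone; adjusted p = 0.216, and adjusted p = 0.95 with an estimated correlation). In infected EC, of 15 lipid genes 4 fell, 1 rose and 10 did not pass (4 and 1 adjusted over the list alone; adjusted p = 0.00259, and adjusted p = 0.398 with an estimated correlation), led by Npc2d (-4.08 ± 0.80) and the lipase mag (-3.76 ± 0.95). In EC of R1, the hormone gene sNPF (7.06 ± 0.18) and the tyrosine hydroxylase gene ple (4.73 ± 0.27) were higher than in the other regions.

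The white gene, w, stood at 0.0922 ± 0.109 RPKM in the 2 uninfected whole-midgut EE libraries and between 4.74 and 116 in the other uninfected whole-midgut libraries. It is a common marker of transgenes, and the EE sort of the whole midgut used a YFP-tagged protein in place of a Gal4 driver with GFP. Whether this difference gave the low level of w was not tested.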
